A study of Mus musculus with 13 samples.

How the data were processed

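Gene expression was measured by RNA sequencing of polyA-selected RNA from mouse skeletal muscle in 13 samples. Per the labels, the animals were either homozygous for a floxed miR-181a2b2 locus (flox, called WT in the sample titles) or systemic knockouts of it (KO). They were fed chow or a diet labelled HFSC, an abbreviation that the labels do not spell out. The groups were chow flox (n = 3), chow KO (n = 3), HFSC flox (n = 4) and HFSC KO (n = 3), assigned from the genotype and diet labels, with replicate numbers from the titles. The labels mention hindlimb ischemia for the series but do not say for any sample which limb was taken or when. The labels' extraction protocol names white adipose tissue, whereas the source label of each sample is skeletal muscle. Each label describes a separate sample, and nothing says outright that each came from its own animal, so p-values measure the spread between these samples, which may be partly technical.

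The deposited table holds raw counts of reads per Ensembl gene. Per the submitters' processing notes, the authors used Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 with build GRCm38. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. Reads from a gene and from an overlapping or antisense partner can therefore not be told apart, and near-identical copies may share reads. Of 49315 gene identifiers, 49056 were matched to GENCODE M21 for symbols and GRCm38 coordinates, and 259 have no symbol. All 13 count columns belong to a sample by name.

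Total counts ran from 20830943 to 45710227 per library, with a median of 29011060. A gene with no read in a library is limited to 3 counts, between 0.0656 and 0.144 CPM, the standard unit of counts scaled to a common library total. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. No pair of replicates agreed within sampling noise: over genes with at least 20 counts in a pair, chi-square per degree of freedom ran from 10.5 to 193.

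Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust fits. All 13 libraries entered 1 model with 4 group means and no covariate. Library sizes were scaled by trimmed mean of M values (TMM), and edgeR's filterByExpr kept 16496 genes. P-values were adjusted by Benjamini-Hochberg over these genes with a threshold of 0.05. Standard errors (SE) of log2 fold changes were computed as the fold change over the square root of F. CPM values use TMM library sizes and are given as mean ± SD. Of 29 gene lists written down in advance, 25 with at least 5 tested genes were tested with camera in limma 3.58.1. The lists of the miR-181 locus and of sex-linked genes were kept out of that test by design, and the neutrophil and skin keratinocyte lists had fewer than 5 tested genes. The test used log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, and was adjusted over the lists in each contrast. Counts of list members were also made with the adjustment over the list alone.

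Seed sites were matches to TGAATGTA, the 8-base site of miR-181-5p, in the longest annotated 3' UTR of each gene. They were compared by camera, adjusted over the 3 genotype contrasts, with genes that have an annotated 3' UTR and no such site, and with 100 random 8-base motifs of the same composition. Alternatives were size factors by relative log expression (RLE), DESeq2 1.42.0, limma voom with sample quality weights, no low-count filter and the replicate number as a block. Others were only the groups compared in the fit, leaving out each library, camera with an estimated correlation, and fry. Scaling by library totals with no TMM factors was added after the data had been examined. On simulated counts for 16496 genes in the contrast of KO and flox on chow, the edgeR test recovered 16.4% of genes changed 1.5-fold, 49.3% of those changed 2-fold and 93.9% of those changed 4-fold. For the contrast on HFSC these shares were 17.9%, 64.2% and 98.5%. The changed genes were drawn from those with a mean of at least 1 CPM. Counts were simulated independently for each gene, with no spread shared by the genes of a library, so these shares need not hold for the real libraries.

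The genes named were fixed by a rule before the data were examined. For each of the 4 contrasts between a pair of groups it takes the 8 that rose and the 8 that fell with the smallest p, among called genes with a mean of at least 1 CPM in a group, no overlap between the groups' libraries and a symbol that is not a predicted or clone name. With fewer than 5 calls it takes the 5 genes with the smallest p. It adds up to 5 genes per direction for the averaged and interaction contrasts, the locus genes and Cxcr4 in genotype contrasts, and up to 4 members of each called list in the direction of the call. Other members of a list are named as list members.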

Results

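RNA sequencing of skeletal muscle from miR-181a2b2 flox and KO mice on chow or HFSC diet was used to ask how loss of this microRNA locus and the diet alter muscle gene expression. There were 3 chow flox, 3 chow KO, 4 HFSC flox and 3 HFSC KO libraries, with 20830943 to 45710227 counts each. Myh4, the myosin heavy chain of fast glycolytic fibres, had the most counts in all libraries except HFSC KO replicate 4, where mt-Co1 had the most. The first principal component of log2 CPM held 50.7% of the variance. It placed the 3 chow KO libraries and chow flox replicate 4 on one side, at 51.3 to 88.6, and the other 9 libraries on the other, at -67.8 to -13.3.

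The targeted locus was examined first. Mir181a-2 (chromosome 2, 38852735 to 38852810, plus strand) had 2, 1 and 0 reads in chow flox replicates 2, 3 and 4, and 1, 0, 0 and 0 reads in HFSC flox replicates 1 to 4. It had 0 reads in all 6 KO libraries, and Mir181b-2 (38853830 to 38853918) had 0 reads in all 13. These counts are at or under the floor of 3 counts and do not check the genotype labels. The neighbouring antisense transcript Nr6a1os (38823257 to 38852370, plus strand) lies within Nr6a1 (38723370 to 38927688, minus strand), so their reads cannot be told apart without a strand setting. In chow KO, Nr6a1os was higher than in chow flox by 1.36 ± 0.35 on the log2 scale (adjusted p = 0.031), while Nr6a1 differed by 0.77 ± 0.24 and did not pass (adjusted p = 0.059). On HFSC neither passed, with log2 fold changes of -0.30 ± 0.34 for Nr6a1os (adjusted p = 0.82) and -0.07 ± 0.23 for Nr6a1 (adjusted p = 0.95).

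To ask how the KO libraries differed on chow, chow KO was compared with chow flox. Transcripts of connective tissue, macrophages and dividing cells were lower in chow KO. Of the 18 fibroblast and extracellular matrix genes, 17 fell (18 adjusted over the list alone), with a median log2 fold change of -2.72 (camera, adjusted p = 1.7e-12). This call and those of the other lists given here for chow KO were lost with an estimated correlation (adjusted p = 0.593 with an estimated correlation for each). Col3a1, which encodes a fibrillar collagen (chromosome 1, 45311538 to 45349706), fell from 1362 ± 999 CPM (SD, n = 3) to 102.7 ± 44.8 CPM, a log2 fold change of -3.73 ± 0.54 (SE). Col6a2 (-2.25), Col5a1 (-2.77) and Pdgfra, a receptor of fibroblast-like progenitors (-1.28), fell as well. Of the 21 monocyte and macrophage markers, 19 fell (20 adjusted over the list alone), with a median of -3.03 (camera, adjusted p = 3.6e-10). Csf1r, the receptor for the macrophage growth factor CSF1, fell from 33.7 ± 21.9 to 6.33 ± 1.62 CPM, and Ms4a7 (-4.25), C1qc (-2.46) and C1qb (-2.74) fell too. Of 21 cell cycle genes 11 fell (camera, adjusted p = 8.6e-05), among them Top2a (-3.49), Mcm5 (-1.69) and Mki67 (-3.04). The interferon response list had 12 of 18 members lower (camera, adjusted p = 1.3e-06), with Irf7 at -2.02, Oas1a at -2.57, Ifi44 at -2.23 and Bst2 at -1.45. Of 11 lymphocyte markers 6 fell (camera, adjusted p = 0.0060), including the T-cell gene Cd4, from 2.20 ± 2.65 to 0.170 ± 0.132 CPM, where chow KO lay near the floor of 3 counts. Of 20 endothelial markers 4 fell (camera, adjusted p = 0.00034), namely Sox17 (-0.68), Plvap (-1.06), Cdh5 (-0.82) and Pecam1 (-0.74). Cxcr4, the chemokine receptor in the series title, fell by 1.86 ± 0.49 on the log2 scale (adjusted p = 0.033), from 10.3 ± 8.49 to 2.85 ± 0.0499 CPM. Chow flox replicates 2, 3 and 4 had 8.34, 19.6 and 2.93 CPM of Cxcr4, and the chow KO libraries 2.80 to 2.90 CPM. For Cxcr4, KO against flox on chow, the log2 fold change without chow flox replicate 3 was -1.03 (adjusted p = 0.186), and the call was also lost without chow flox replicate 2 or any 1 chow KO library (adjusted p from 0.063 to 0.130).

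Other genes that fell in chow KO were the matrix genes Fbln7 (-1.83), Mfap4 (-3.37), Pamr1 (-2.85) and Cpxm1 (-2.50), and Ace, which encodes angiotensin-converting enzyme (-0.89). Among the genes that rose, Cdh4, a cadherin, went from 4.88 ± 3.20 to 26.0 ± 8.33 CPM (log2 fold change 2.43 ± 0.46). Tbc1d4, a regulator of insulin-stimulated glucose uptake, rose by 0.73 ± 0.16, and Bckdhb, a subunit of the branched-chain keto acid dehydrogenase, by 0.63 ± 0.13. Isoc2a (0.56), Taf10 (0.55), Rab5if (0.66), Plet1os (1.71) and Nfkbib (0.52) also rose. Of 24 genes of fatty acid uptake and oxidation 3 rose, and Lpl, lipoprotein lipase, went from 643 ± 141 to 1124 ± 21.3 CPM (0.81 ± 0.19).

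In total 1898 of 16496 genes passed, 228 higher and 1670 lower in chow KO. Camera called 12 lists, 4 higher (fast fibre, fatty acid oxidation, oxidative phosphorylation and glycolysis) and 8 lower (those above and the cytokine and muscle regeneration lists). None of the 12 passed with an estimated correlation. By fry the matrix (adjusted p = 0.022) and macrophage (adjusted p = 0.030) lists passed. With library totals in place of TMM factors the median log2 fold change of all genes moved by -0.34, with 80 genes higher and 3016 lower, and the lymphocyte, cytokine, muscle regeneration and oxidative phosphorylation lists were not called. The chow flox libraries were spread widely: the median level of the matrix list, relative to the mean of all libraries, was 0.64 and 1.63 in replicates 2 and 3 and -0.75 in replicate 4, against -1.61, -1.86 and -2.57 in chow KO. Chow flox replicate 4 also had low macrophage (-0.86) and cell cycle (-0.99) levels. In chow KO these ran from -2.11 to -1.20 and from -1.38 to -1.03. Chow flox replicates 2 and 3 thus carried most of the cell cycle fall, and of the lymphocyte fall (-1.55 to -0.94 in chow KO). Replicate 4 was at -0.89 for the lymphocyte list. Its endothelial level (-0.64) lay within that of chow KO (-0.68 to -0.48), as did its interferon level (-0.86 against -1.11 to -0.51) and its CPM of Plvap, Pecam1, Irf7, Oas1a, Ifi44, Bst2 and Cd4, so these differences were carried by chow flox replicates 2 and 3. The same held for the levels of the fast fibre, muscle regeneration, oxidative phosphorylation, glycolysis and cytokine lists, where chow flox replicate 4 lay within the chow KO range or, for the last 2, past its far end. For KO against flox on chow, no gene passed when chow flox replicate 3, chow KO replicate 2 or chow KO replicate 3 was left out. The count was 452 without chow flox replicate 2, 929 without chow KO replicate 1 and 7261 without chow flox replicate 4. With only these 2 groups in the fit, 2 genes passed.

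**Figure D1:**
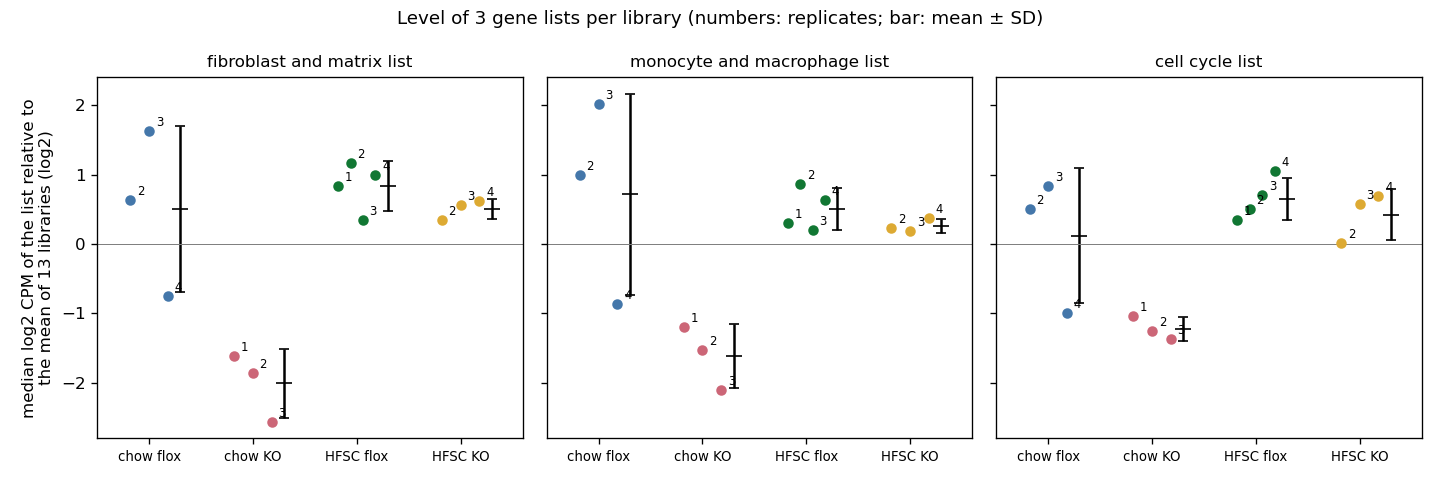
Median log2 CPM of the fibroblast and matrix, monocyte and macrophage, and cell cycle lists in each library, relative to the mean of 13 libraries (log2 scale). Points are libraries numbered by replicate and bars are mean ± SD; chow flox replicate 4 lies at -0.75, -0.86 and -0.99, below the other chow flox libraries and above the chow KO libraries.

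To ask whether the same comparison held on HFSC, HFSC KO was compared with HFSC flox. The 3 genes that passed were all higher in KO. Hspa12b, a heat shock protein family member (chromosome 2, 131127280 to 131146321), rose from 23.8 ± 0.943 (n = 4) to 38.6 ± 3.04 CPM (n = 3), a log2 fold change of 0.70 ± 0.09. Hba-a1, an alpha globin gene, rose from 13.6 ± 2.40 to 32.0 ± 3.96 CPM (1.23 ± 0.16). Myh6, the alpha myosin heavy chain best known from the heart, had 2.33 ± 1.08 CPM in HFSC flox and 9.90 ± 0.995 CPM in HFSC KO (2.11 ± 0.29). Chow flox libraries had 7.45 to 10.3 CPM of Myh6 and chow KO libraries 9.44 to 12.5 CPM. For this gene HFSC KO thus lay near the chow level and HFSC flox was the low group. The adjusted p was 0.035 for each of the 3 genes. Hba-a1 has a near-identical copy, Hba-a2, so its reads are uncertain. Hbb-bs (1.12 ± 0.17) and the endothelial factor Sox17 (0.92 ± 0.14) did not pass (adjusted p = 0.068 for both). Cxcr4 had a log2 fold change of 0.77 ± 0.44 (adjusted p = 0.58). Its interaction of genotype and diet was 2.63 ± 0.65 and did not pass (adjusted p = 0.069).

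Camera called 7 lists on HFSC. Of 6 red blood cell transcripts 1 rose (6 adjusted over the list alone), with a median of 1.02 (camera, adjusted p = 3.6e-10; fry, adjusted p = 0.015). The adipocyte (median 0.65), endothelial (0.28), fatty acid oxidation (0.21), oxidative phosphorylation (0.22) and atrophy and autophagy (0.29) lists were higher and the immediate early list (-0.39) lower, with no member past the threshold over all genes. None of the 7 lists was called with an estimated correlation (adjusted p from 0.307 to 0.974), and the levels of HFSC KO and HFSC flox libraries overlapped for all but the red blood cell and immediate early lists. The matrix list had a median of -0.38 and the macrophage list one of -0.36, neither called. For KO against flox on HFSC, 0 genes passed without HFSC flox replicate 3, HFSC KO replicate 3 or HFSC KO replicate 4, 1 without HFSC flox replicate 1 or 2, 8 without HFSC KO replicate 2 and 12 without HFSC flox replicate 4. DESeq2 called 165 genes, and no gene passed in edgeR with these 2 groups alone in the fit or with library totals.

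To ask what the diet did, HFSC flox was compared with chow flox. Slow fibre transcripts fell. Of 11 slow fibre contractile genes 8 fell (9 adjusted over the list alone), with a median log2 fold change of -2.56 (camera, adjusted p = 1.4e-20; adjusted p = 0.0726 with an estimated correlation). Myh7, the slow myosin heavy chain (chromosome 14, 54970684 to 54994626), fell from 2991 ± 521 to 280 ± 182 CPM (-3.42 ± 0.40). Tpm3, slow tropomyosin, fell from 655 ± 182 to 111 ± 12.6 CPM (-2.56 ± 0.18). Myl3 (-2.55 ± 0.27) and Atp2a2, the slow fibre calcium pump (-2.24 ± 0.28), fell too, as did the troponin genes Tnnc1 (-2.95) and Tnnt1 (-2.61). Of 15 circadian clock genes 2 rose and 4 fell (camera, adjusted p = 0.013; adjusted p = 0.370 with an estimated correlation). Per2 fell from 34.7 ± 6.26 to 9.99 ± 0.596 CPM (-1.79 ± 0.19), Per3 (-1.33), Ciart (-1.40) and Cry2 (-0.73) fell, and Arntl, the activator of the clock, rose from 6.61 ± 2.90 to 24.0 ± 5.01 CPM (1.87 ± 0.28). Ccn1, a matricellular growth factor gene, rose by 1.68 ± 0.20. Smoc2 (0.56), Mcc (0.96), Efr3b (0.76), Ptprg (0.59), mt-Tl1 (1.79) and Erfe (1.97), which encodes erythroferrone, rose as well. Rspo3 (-1.95), Cyp2e1 (-2.10) and Abcc1 (-0.69) fell.

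In total 69 genes passed, 19 higher and 50 lower, or 9 higher and 47 lower with library totals. Of 24 fatty acid genes 0 passed over all genes and 17 were higher when adjusted over the list alone (median 0.61), among them Plin5 at 1.35 ± 0.28 (adjusted p = 0.061) and Pdk4 at 1.59 ± 0.36 (adjusted p = 0.084). Camera called 10 lists, none with an estimated correlation, where the lists other than the slow fibre list had adjusted p from 0.237 to 0.928. By fry the slow fibre (adjusted p = 0.00052) and fatty acid (adjusted p = 0.036) lists passed. For HFSC against chow in flox, 15, 29 and 1456 genes passed without chow flox replicates 2, 3 and 4, and 39, 45 and 17 without HFSC flox replicates 1, 3 and 4. With only the 2 groups in the fit 4 genes passed.

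In KO mice, HFSC was compared with chow in the same way. Slow fibre genes fell here as well, 9 of 11, with a median of -2.63 (camera, adjusted p = 5.5e-08). This call and those of the matrix, endothelial, cell cycle, macrophage and clock lists in KO were lost with an estimated correlation (adjusted p = 0.472 with an estimated correlation for each). Myh7 fell from 3242 ± 155 to 163 ± 59.7 CPM (-4.32 ± 0.47), Tpm3 from 1000 ± 86.6 to 88.9 ± 9.62 CPM (-3.49 ± 0.21), and Atp2a2 (-2.70) and Myl3 (-2.54) fell. Matrix genes rose, 17 of 18, with a median of 2.43 (camera, adjusted p = 9.2e-10). Pdgfra rose from 13.4 ± 2.04 to 48.3 ± 7.77 CPM (1.85 ± 0.18), Col3a1 from 102.7 ± 44.8 to 1064 ± 129 CPM (3.37 ± 0.53), and Col6a1 (2.31) and Col6a2 (2.32) rose. Of 20 endothelial markers 17 rose and 1 fell (camera, adjusted p = 6.7e-08), with Sox17 at 1.23, Ptprb at 0.99, Cdh5 at 1.49 and Tie1 at 1.36. Of 21 cell cycle genes 16 rose and 2 fell (camera, adjusted p = 0.00016), with Rrm2 at 2.40. Of 21 macrophage markers 12 rose (camera, adjusted p = 6.1e-06), including Mrc1 (1.82), Csf1r (1.92) and C1qb (2.26). In flox these lists had medians of 0.07 (matrix), 0.28 (endothelial), 0.25 (cell cycle) and -0.54 (macrophage). None of their members passed there. The matrix level was -2.57 to -1.61 in chow KO, 0.35 to 0.63 in HFSC KO and 0.34 to 1.17 in HFSC flox. The rise of the matrix list in KO thus starts from the same low chow KO libraries as the genotype contrast on chow. Of 15 clock genes 8 fell and 2 rose (camera, adjusted p = 0.013), with Hlf falling from 39.0 ± 4.29 to 3.97 ± 0.428 CPM (-3.30 ± 0.37) and Per2 by 1.03 on the log2 scale.

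Further genes that rose in KO on HFSC were Scara5 (1.79), Hspa12b (1.02), Cyp1b1 (3.85), Tinagl1 (1.77), Mcc (1.47), Fbln7 (2.22) and Col4a1, a basement membrane collagen (3.06). Fgf2, a fibroblast growth factor, fell by 1.54 on the log2 scale, and Emx2 (-2.91) and Nlrc3 (-1.99) fell. Angptl4, an inhibitor of lipoprotein lipase, rose by 3.13 ± 0.44 and Pdk4 by 1.72 ± 0.38, among 24 fatty acid genes of which 6 rose and 1 fell. Of 13 adipocyte markers 7 rose too, with a median of 1.20 (camera, adjusted p = 0.0012, or 0.472 with an estimated correlation). In total 4201 genes passed, 2459 higher and 1742 lower, or 2407 higher and 1046 lower with library totals. Camera called 16 lists, none of them with an estimated correlation (adjusted p from 0.472 to 0.765), and fry called 12 of them. The groups did not overlap for 50.6% of all tested genes, against 10% by chance for 3 against 3. For HFSC against chow in KO, the count was 2120 without chow KO replicate 2, 1459 without chow KO replicate 3 and 1797 without HFSC KO replicate 4.

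Between the diet contrasts in the flox and KO mice, which share no library, 11 genes were higher in both, against 2.83 expected from lists of these sizes, and 35 were lower in both, against 5.28 expected. Over all 16496 genes the log2 fold changes of these contrasts correlated only weakly (Pearson r = 0.13, Spearman rho = 0.10). Those of the genotype contrasts on chow and on HFSC had a Pearson r of 0.058 and a Spearman rho of -0.12. Averaged over the genotypes, HFSC differed from chow in 2499 genes, 1482 higher and 1017 lower, or 761 higher and 798 lower with library totals. The genes with the smallest p included Mcc (1.21), Ccn1 (1.58), Erfe (2.85), Akap12 (1.14) and Cyp1b1 (2.37), which rose, and Tpm3 (-3.02), Myl3 (-2.55), Myh7 (-3.87), Atp2a2 (-2.47) and Cyp2e1 (-2.34), which fell. Of 14 immediate early genes 4 rose, with Atf3 at 2.49 ± 0.31 and Fosb at 3.35 ± 0.57. Camera called 13 lists here, none with an estimated correlation (adjusted p from 0.284 to 0.488). For HFSC against chow averaged over the genotypes, 4048 genes passed without chow flox replicate 3, 1569 and 1217 without chow KO replicates 2 and 3, 1451 without HFSC flox replicate 4 and 1308 without HFSC KO replicate 4.

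**Figure D2:**
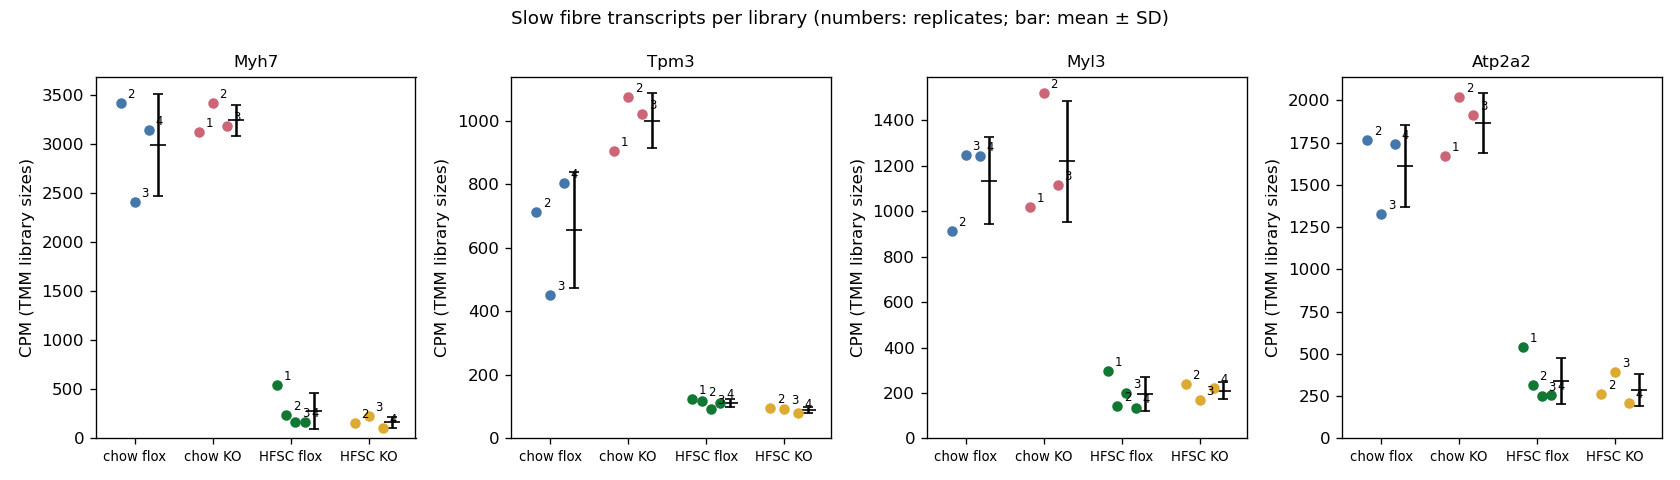
CPM of the slow fibre genes Myh7, Tpm3, Myl3 and Atp2a2 in each library on linear axes from 0. Points are libraries numbered by replicate and bars are mean ± SD; for Myh7 the chow libraries lie between 2410 and 3417 CPM and the HFSC libraries between 106 and 548 CPM.

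In the contrast of KO against flox averaged over the diets, no gene passed with edgeR, although 3594 had an unadjusted p under 0.05 and the smallest adjusted p was 0.0678. DESeq2 called 1408 genes and limma voom 6505. Camera called 14 lists, 6 higher and 8 lower, with the matrix list at a median of -1.65 and the macrophage list at -1.73 lower and the red blood cell list at 0.64 higher, none of the 14 with an estimated correlation (adjusted p from 0.333 to 0.476). Col3a1 had a log2 fold change of -2.08 ± 0.35 and Cxcr4 one of -0.55 ± 0.33 (adjusted p = 0.068 and 0.34). The genotype by diet interaction gave 0 genes with edgeR, with 4811 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0625. DESeq2 called 2025 and limma voom 7098. Camera called 7 lists in the interaction, none with an estimated correlation (adjusted p = 0.834 and above). Without chow flox replicate 4, edgeR called 4824 genes for the averaged genotype contrast and 5928 for the interaction, and without HFSC flox replicate 4 it called 9 and 2.

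To ask whether messages with a miR-181 site were higher in KO, 878 genes with the site were compared with 13060 without it. By its label the genotype leaves miR-181c, miR-181d and the other miR-181a/b cluster in place. A small difference would therefore not show that targets of the lost microRNAs are unaffected. On chow the medians differed by 0.04 on the log2 scale (limma camera, adjusted p = 0.544), and 53 of 100 random motifs gave a difference as high or higher. On HFSC the site genes were lower in KO, by -0.08 (limma camera, adjusted p = 0.011), and 69 of 100 random motifs gave a difference as high or higher. The random motifs on HFSC ran from -0.12 to -0.03 with a median of -0.07, so genes with other motifs of the same composition were lower as well. Averaged over the diets the difference was -0.02 (limma camera, adjusted p = 0.497). The list of described miR-181 targets was not called in any contrast, with 0 of 21 members higher and 2 lower in chow KO and 0 either way on HFSC.

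The mitochondrial gene mt-Nd3, a complex I subunit, was singled out after its values were seen. It had 861 to 1561 reads in 6 flox libraries, 39 to 45 in the 6 KO libraries and 114 in HFSC flox replicate 4. Gm28438, a nuclear pseudogene copy (chromosome 1, 24612775 to 24613119), had 25 to 83 reads in those 6 flox libraries, 931 to 1411 in KO and 2285 in HFSC flox replicate 4. The sequences differ at 1 of 345 bases, the third base of mt-Nd3, at position 9461 of the mitochondrial genome, so reads of both are uncertain as expression. The share of mt-Nd3 in the reads of both was 94.3% to 97.9% in the 6 flox libraries and 2.69% to 4.23% in KO. In HFSC flox replicate 4 it was 4.75% (95% Wilson interval 3.97% to 5.68%).

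**Figure D3:**
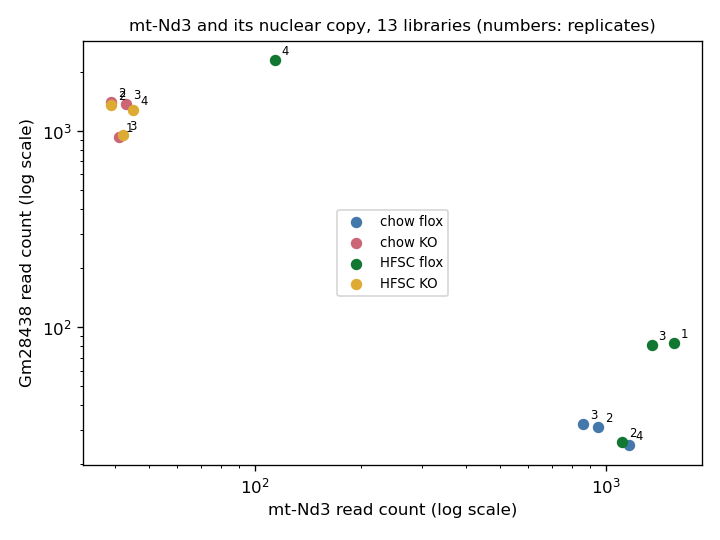
Read counts of mt-Nd3 (horizontal, log scale) and its nuclear copy Gm28438 (vertical, log scale) in 13 libraries, coloured by group and numbered by replicate. HFSC flox replicate 4, with 114 and 2285 reads, lies with the 6 KO libraries and apart from the other flox libraries.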

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

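Of the tests given here, that of the position of HFSC flox replicate 4 and the counts of other splits of the libraries were planned before their results were seen. The tests of the other explanations were chosen only after the result was seen.

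In 4 of 80 measures taken over the 4 HFSC flox libraries, 1 library lay far from the other 3 by Dixon's 95% critical value for the gap over the whole range. Chance flags about 1 in 20 groups. The measures were Isoc2a (gap 0.857 of the range, replicate 1 at 17.4 CPM against 19.7 to 20.1), the muscle regeneration list (0.891, replicate 1 at 0.90 against 0.12 to 0.20), the fatty acid uptake and oxidation list (0.841, replicate 4 at 0.41 against -0.0049 to 0.060) and the percentage of mt-Nd3 (0.964, replicate 4). In the genotype by diet interaction, camera called 7 lists, and 72 of 100 splits of the libraries, the real one included, gave at least as many. Their median interactions were 2.72 for macrophage markers, 2.16 for matrix genes, 1.88 for the cell cycle, 1.503 for interferon genes, 1.03 for adipocyte markers, 0.97 for endothelial markers and 0.92 for red blood cell transcripts. None was called with an estimated correlation.

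The lower matrix and macrophage transcripts of chow KO were shared in part by chow flox replicate 4. A KO animal of the same maternal type under that label was argued against, since mt-Nd3 took 97.9% of the reads of it and its nuclear copy there, against 2.69% to 4.23% in KO. The TMM factors were argued against as the whole cause, since the 39 matrix and macrophage genes had a median log2 difference of -2.66 with library totals (log2 CPM, prior count 2), which moved the median of all genes by -0.34, against -2.77 in edgeR with TMM factors. These medians of the matrix and macrophage genes come from different estimators, so the step between them does not measure the effect of the scaling. A like loss of all cells other than muscle fibres was also argued against, since the medians of 6 cell type lists lay up to 3.44 apart on the log2 scale, from Schwann cells to macrophages. The Schwann end rested on chow KO replicate 1, at a level of 0.98 against -0.31 and -0.08 in chow KO replicates 2 and 3. Apart from it, the endothelial, smooth muscle and adipocyte medians (-0.56, -0.56 and -0.53) lay above those of matrix genes (-2.72) and macrophages (-3.03). An effect of the genotype, or differences between the animals or pieces of muscle that happen to lie between these 6 libraries, may each account for the lower matrix and macrophage transcripts, and neither is excluded. The share of mt-Nd3 was 2.69% to 4.22% in all chow KO and 96.4% to 97.9% in all chow flox libraries. Whatever that share marks can therefore not be told apart from the genotype on chow.

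The lower slow fibre transcripts on HFSC were present in both genotypes. A loss of all fibre transcripts was argued against by a gap of 2.51 between the fast and slow fibre medians. A different piece or mix of muscles taken on each diet cannot be told apart from an effect of the diet, because the lowest chow library lay 1.28 above the highest HFSC library and no label gives the muscle.

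Counts of mt-Nd3 were low and those of its nuclear copy high in the KO libraries and in HFSC flox replicate 4. KO and flox differed by 0.0280 on the log2 scale in the sum of both, -4.20 in mt-Nd3 and 4.17 in Gm28438, or by 0.0805, -4.77 and 4.91 without HFSC flox replicate 4, an alternative chosen after seeing the data. A sum that hardly differs is consistent with a mitochondrial variant that moves reads to the copy, a hypothesis that needs the reads and leaves the counts of neighbouring genes, which differed too, untested. A difference of at least 2-fold at Nnt, a nuclear gene that marks some strains, was not found within either diet: KO over flox was 1.67 on chow, with no overlap (327 to 376 against 173 to 277 CPM), and 0.879 on HFSC, with overlap (126 to 148 against 141 to 167 CPM). The level of Nnt was also lower on HFSC than on chow within each genotype. A bound on that level can therefore not tell whether KO and flox differ in strain background. Whether HFSC flox replicate 4 is a mislabelled KO animal cannot be told apart: its median position from flox (0) to KO (1) was 0.383, which met the bound set beforehand against that explanation, but that bound was wrong because KO libraries left out in turn lay at 0.344 to 0.937, overlapping the other flox libraries at 0.0585 to 0.413.

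Other splits of the same libraries were tried for each count. For KO against flox on chow (10 splits) and HFSC against chow in KO (10 splits) they are too few for a share under 0.05. On chow, 2 splits gave at least the real 1898 genes (highest other 3148), 4 gave at least 12 lists (highest other 14) and 1, the real one, gave the seed site difference of 0.04 (highest other 0.03). In KO, 1 split gave 4201 genes (highest other 0) and 2 gave 16 lists (highest other 16). For KO against flox on HFSC (35 splits), chance could not be excluded for the 3 genes (2 splits, highest other 10) or the 7 lists (19 splits, highest other 10). The split with 10 genes set replicates 1 to 3 of flox against the rest, as the share of mt-Nd3 does. For the size of the seed site difference, 0.08, only the real split reached it (highest other 0.07), the smallest share that 35 splits can give. Random motifs on HFSC had a median difference of -0.07, and 69 of 100 were as high or higher. The size of the difference therefore does not point to the miR-181 site. For HFSC against chow in flox (35 splits) chance could not be excluded for the 69 genes (3 splits) or the 10 lists (20 splits, highest other 16), and a split with 650 genes points to a structure of the samples. For HFSC against chow averaged over the genotypes (100 splits drawn) 3 splits gave at least the real 2499 genes. That share is under 0.05, but another split gave 6013, again a structure, so chance is not called excluded. Nor was chance excluded for the 13 lists (24 splits, highest other 18). For KO against flox averaged over the diets chance was not excluded for the 14 lists (19 splits, highest other 16) or the seed sites (43 splits, 0.02 against a highest other of 0.05). For the interaction it was not excluded for the 7 lists (72 splits, highest other 17). In both contrasts edgeR called 0 genes, which all 100 splits reach, so the splits could not decide anything for genes. The highest other split gave 27 genes for the averaged contrast (3594 at an unadjusted p under 0.05) and 162 for the interaction (4811).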

How the results depend on the processing

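Scaling by library totals was chosen after seeing the data; the other alternatives were planned. For named genes, 4816 values kept their direction and side of the threshold, 534 fell short of it, 364 newly passed it and 2 changed sign; for lists these were 926, 196, 0 and 2. RLE factors moved no count of genes or lists by over 1.5 times. Replicate numbers did not pair the samples, since same-numbered libraries of the groups compared had correlations from -0.341 to 0.0776, so the replicate block is given only here. Depth limits a gene with no read to 3 counts. Except where fewer libraries or genes entered, the cause was not tested.

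In the order KO against flox on chow, KO against flox on HFSC, HFSC against chow in flox, HFSC against chow in KO, KO against flox averaged over the diets, HFSC against chow averaged over the genotypes and genotype by diet interaction, edgeR called 1898, 3, 69, 4201, 0, 2499 and 0 genes. DESeq2 called 3256, 165, 392, 5273, 1408, 3551 and 2025, and limma voom with sample quality weights called 9899, 33, 4176, 7160, 6505, 5770 and 7098. On simulated counts for KO against flox on HFSC, 21.2% of DESeq2's calls and 7.53% of edgeR's were unchanged genes. With library totals edgeR called 3096, 0, 56, 3453, 2, 1559 and 0. With the replicate block KO against flox on chow gave 0, KO against flox on HFSC 0, HFSC against chow in KO 2382 and HFSC against chow averaged over the genotypes 1504. With only the 2 groups compared in the fit, KO against flox on chow gave 2, KO against flox on HFSC 0 and HFSC against chow in flox 4. With no low-count filter KO against flox on HFSC gave 22, KO against flox averaged over the diets 40 and the genotype by diet interaction 161. Leaving out 1 library in turn gave, in the order above, 0 to 7261, 0 to 12, 15 to 1456, 1459 to 2975, 0 to 4824, 1217 to 4048 and 0 to 5928 genes.

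For gene lists, camera called 12, 7, 10, 16, 14, 13 and 7. Camera with an estimated correlation called 0 in each of the 7 contrasts. Fry, which does not compare a list with other genes, called 2, 1, 2, 12, 5, 9 and 0. With the replicate block the genotype by diet interaction gave 14 lists. Leaving out 1 library gave 10 to 14, 7 to 10, 9 to 11, 12 to 16, 13 to 17, 11 to 16 and 6 to 13 lists.

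Camera's direction for 2 lists called higher turned to lower without chow flox replicate 4. Over the libraries left out in turn, the adjusted p of the list endothelial markers, HFSC against chow in flox, ran from 3.4e-04 to 0.944 and that of the list fibroblast and extracellular matrix, HFSC against chow in flox, from 2.6e-08 to 0.316, the highest being those without chow flox replicate 4. Nr6a1 in KO against flox on HFSC ran from -0.20 to 0.12 and changed sign without HFSC flox replicate 4 (0.12) and HFSC KO replicate 2 (0.10). For the overlap of calls between the genotype contrasts, DESeq2 gave 4 genes higher and 6 lower in both (6.31 and 8.95 expected), and edgeR's 3 calls on HFSC were too few for an overlap to be expected. For the diet contrasts, an adjusted p threshold of 0.1 gave 37 and 63 (13.8 and 15.6 expected) and DESeq2 94 and 99 (34.9 and 27.9 expected), against 11 and 35. The seed site difference without 1 library ran from 0.03 to 0.05 on chow, from -0.09 to -0.06 on HFSC and from -0.04 to -0.01 averaged.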

Other observations

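In chow KO, 6 of 20 angiogenic factors and receptors fell, 1 rose and 13 did not pass against chow flox, and camera did not call the list (adjusted p = 0.053; adjusted p = 0.593 with an estimated correlation). The members that fell included Apln, the ligand of the apelin receptor (-2.61 ± 0.42), its receptor gene Aplnr (-2.02 ± 0.56) and Angpt2 (-1.59 ± 0.32), while Fgf2 rose (0.54 ± 0.14). Chow flox replicate 4 had 6.06 CPM of Aplnr, within chow KO (3.62 to 8.46 CPM). The fall of Aplnr was thus carried by chow flox replicates 2 and 3 (25.3 and 33.4 CPM). In KO mice on HFSC against chow, 10 rose and 2 fell (camera, adjusted p = 0.038; adjusted p = 0.472 with an estimated correlation), with Apln at 3.38 ± 0.43, Pgf at 1.63 ± 0.29 and Angpt2 at 1.45 ± 0.32. Of the 4 neutrophil markers tested 1, Csf3r, fell in chow KO, where 1 library had no read of it. Its level in chow flox replicate 4, 0.229 CPM, lay within chow KO (0 to 0.443 CPM). The fall of Csf3r was thus carried by chow flox replicates 2 and 3 (2.598 and 12.953 CPM).

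Over both genotypes, 13 of 15 clock genes passed on HFSC against chow, 3 higher and 10 lower (camera, adjusted p = 0.0034; adjusted p = 0.379 with an estimated correlation). The activators Npas2 (2.78 ± 0.36), Arntl (1.497 ± 0.20) and Clock (0.53 ± 0.10) rose and the output genes Dbp (-1.31 ± 0.20) and Hlf (-2.27 ± 0.24) fell. Of 16 atrophy and autophagy genes 6 rose (camera, adjusted p = 0.014; adjusted p = 0.379 with an estimated correlation), among them the metallothionein gene Mt2 (2.35 ± 0.36) and the ubiquitin ligase gene Trim63 (1.05 ± 0.23). The time of day at which muscle was taken is given by no label. Of 4 sex-linked transcripts tested, 0 passed in either genotype contrast by edgeR, and 1, Eif2s3y, was lower on HFSC over both genotypes (-0.34 ± 0.08).

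The reads of mt-Tg, the transfer RNA gene next to mt-Nd3, numbered 107 to 181 in the flox libraries other than HFSC flox replicate 4 and 0 in that library and in all 6 KO libraries. Those of mt-Tr, in the same order, were 64 to 89, 3 and 1 to 9. For mt-Nd4l they were 100 to 198, 155 and 42 to 57. Scaled by library totals, HFSC flox replicate 4 had 3.39 CPM of mt-Nd4l, between the KO libraries (1.38 to 1.96) and the other flox libraries (3.80 to 6.85). By TMM library sizes it had 3.27 CPM, at the low end of the other flox libraries (3.07 to 6.69; KO 1.43 to 2.28). For Gm10222, a pseudogene beside Gm28438 on chromosome 1, the reads in the same order were 27 to 69, 263 and 116 to 165.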
